A study of Homo sapiens with 24 samples.

How the data were processed

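Total RNA of 2 BRAF-mutant human cell lines, SKMEL28 and SW1736, was measured on 24 Illumina bead arrays, 3 for each of 8 groups (each line at 0, 1, 6 and 48 h of 2 µM vemurafenib). Per the labels, cells grew in RPMI with serum, RNA was taken with Trizol and an RNeasy kit with DNase, and biotin-labelled cRNA was made with an Ambion MessageAmp kit. The deposited raw table gives a signal intensity for each probe and array; its values are positive and linear, their medians differ between arrays, and the table does not state how background was treated. Per the file headers, it also gives a detection p-value for each probe and array. The authors also deposited a value table whose values, from their distribution, are log2 and quantile normalized and not centred, although the labels state no scale. Each column matched the raw signal of the same array best, with a median of 6.90 per column. Partek is the tool the submitters' processing notes name, with no version given. Neither table names the chip or a date for an array, and an array's signals carry no count of molecules, so the number of arrays limits the precision.

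Values were computed from the raw signals. Background was corrected with the normexp model of limma, using the detection p-values and an offset of 16, arrays were quantile normalized, and values were put on the log2 scale. Of 47231 probes, those detected at p under 0.05 on at least 3 arrays were kept (26673). By the symbols the platform annotation gives, 30113 probes had 1 gene symbol, 30074 of them matched to a current gene, 8 had several and 17110 had none. Each gene was read from its probe with the highest mean signal, which left 13699 genes. Where the probe of a gene was detected on no array of a group, a called change between 2 groups is given as a bound ("at least N-fold"), while differences in response are given as fitted, with the missing detection named; medians of lists use a bound only where no probe of the gene was detected. Detection is given for that probe unless others are named.

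One linear model with a mean for each of the 8 groups was fitted to all genes with limma (16 residual and 6.34 prior degrees of freedom), and p-values were adjusted by Benjamini and Hochberg within each comparison at 0.05. There were 13 comparisons: each of 3 times against untreated cells in each line, 48 h against 6 h in each line, the difference between lines (SW1736 minus SKMEL28) in each of these 4 changes, and untreated SW1736 against untreated SKMEL28. Each line was treated in its own arrays, so the comparisons of 1 line share its untreated arrays.

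Members of 24 gene lists were written down from general knowledge. Each list was tested with camera (preset correlation 0.01), which compares its genes with all other genes, and again with an estimated correlation and with fry. List p-values were adjusted within families of 144 tests (comparisons with untreated cells), 48 (48 h against 6 h) and 96 (differences between lines). The comparisons, lists, filter, threshold, rule for naming genes and the alternatives named here, unless said otherwise, were chosen before the data were examined.

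Genes were named by a rule. It takes the genes with the largest rises and falls past the threshold in each comparison, up to 8 each way for comparisons with untreated cells and up to 5 for the others, if detected on at least 2 of 3 arrays of both groups and with replicates that do not overlap. Uncharacterised symbols, histone and HLA families and sex-linked marker genes were left out. It adds up to 4 members of each list that passed, up to 2 genes each way given as bounds, and, whether or not they changed, ERBB3, ERBB2, EGFR, DUSP6, SPRY4, CCND1, EGR1, MITF, CTBP1, CTBP2 and the measured ERBB ligands. The text uses fewer, taken from the top.

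The alternatives were no background correction, median scaling, the authors' values, no filter (20046 genes), a stricter filter at p under 0.01 (10890 genes), the mean of a gene's probes, probes counted singly, a 2-fold minimum, an adjusted p under 0.01, each line fitted alone, a trended robust prior, array weights, the replicate number within each line as a fixed block and as a random block, and leaving out each array in turn. The third SW1736 arrays left out together and the other ERBB3 probes were added after the data were seen. The fit was tested on simulated data with known changes: at 6 h in SKMEL28 26.9%, 82.1% and 100% of genes changed by 1.5, 2 and 4-fold were called, in SW1736 34.3%, 68.7% and 100%, and for the difference between lines 9.85%, 46.2% and 96.2%. A simulated shift of 0.5 in the 22 lysosome and autophagy genes at 48 h in SW1736 was called (camera adjusted p 3.92e-15), with 1 of 143 other tests. Simulated genes were independent, so the preset correlation was not tested. Software was R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15 and matplotlib 3.10.9. Probes without a symbol were left out of the comparisons of genes.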

Results

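Gene expression of 2 BRAF-mutant cancer lines, the melanoma line SKMEL28 and the thyroid cancer line SW1736, was measured on 24 Illumina bead arrays. Cells were left untreated (0 h) or given 2 µM vemurafenib, an inhibitor of mutant RAF kinase, for 1, 6 or 48 h, with 3 arrays for each line and time. The series is about relief of feedback on transcription of ERBB3 (HER3), a receptor tyrosine kinase, by RAF and MEK inhibitors, so each time was set against untreated cells of its line, 48 h against 6 h, and the response of SW1736 against that of SKMEL28. Between 17369 and 19843 probes were detected per array (36.8% to 42.0%). Nothing in the labels says that the 3 replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Changes are log2 differences ± SE from 3 arrays per group, and adjusted p-values are those of limma over 13699 genes.

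More genes changed with time in both lines. With untreated arrays at 0 h only, drug and culture time cannot be told apart. In SKMEL28, 24 genes changed at 1 h (5 higher, 19 lower), 938 at 6 h (360 higher, 578 lower) and 5328 at 48 h (2746 higher, 2582 lower). In SW1736 the counts were 29 (5 higher, 24 lower), 1193 (552 higher, 641 lower) and 4692 (2487 higher, 2205 lower). Scaling arrays by their median instead of by quantiles gave 159 higher and 723 lower genes in SKMEL28 and 228 higher and 688 lower in SW1736 at 6 h, and 1856 higher against 2724 lower and 1596 higher against 2378 lower at 48 h; with it the median of all genes moved to -0.13 in SKMEL28 at 6 h. SW1736 replicates were noisier than SKMEL28 replicates (median SD 0.234 against 0.147). In simulation the shared spread estimate made 33.5%, 32.5% and 31.0% of 197, 200 and 203 SW1736 calls false at 1, 6 and 48 h. With SW1736 fitted alone 6.19%, 3.13% and 3.70% were false. The false share depends on how many genes truly change, so these shares are not estimates for the real lists, which differ in size. Fitted alone, SKMEL28 had 34, 1832 and 6552 changed genes at these times and SW1736 4, 489 and 3438. At 1 h and 6 h this reversed the lines' order.

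**Figure D1:**
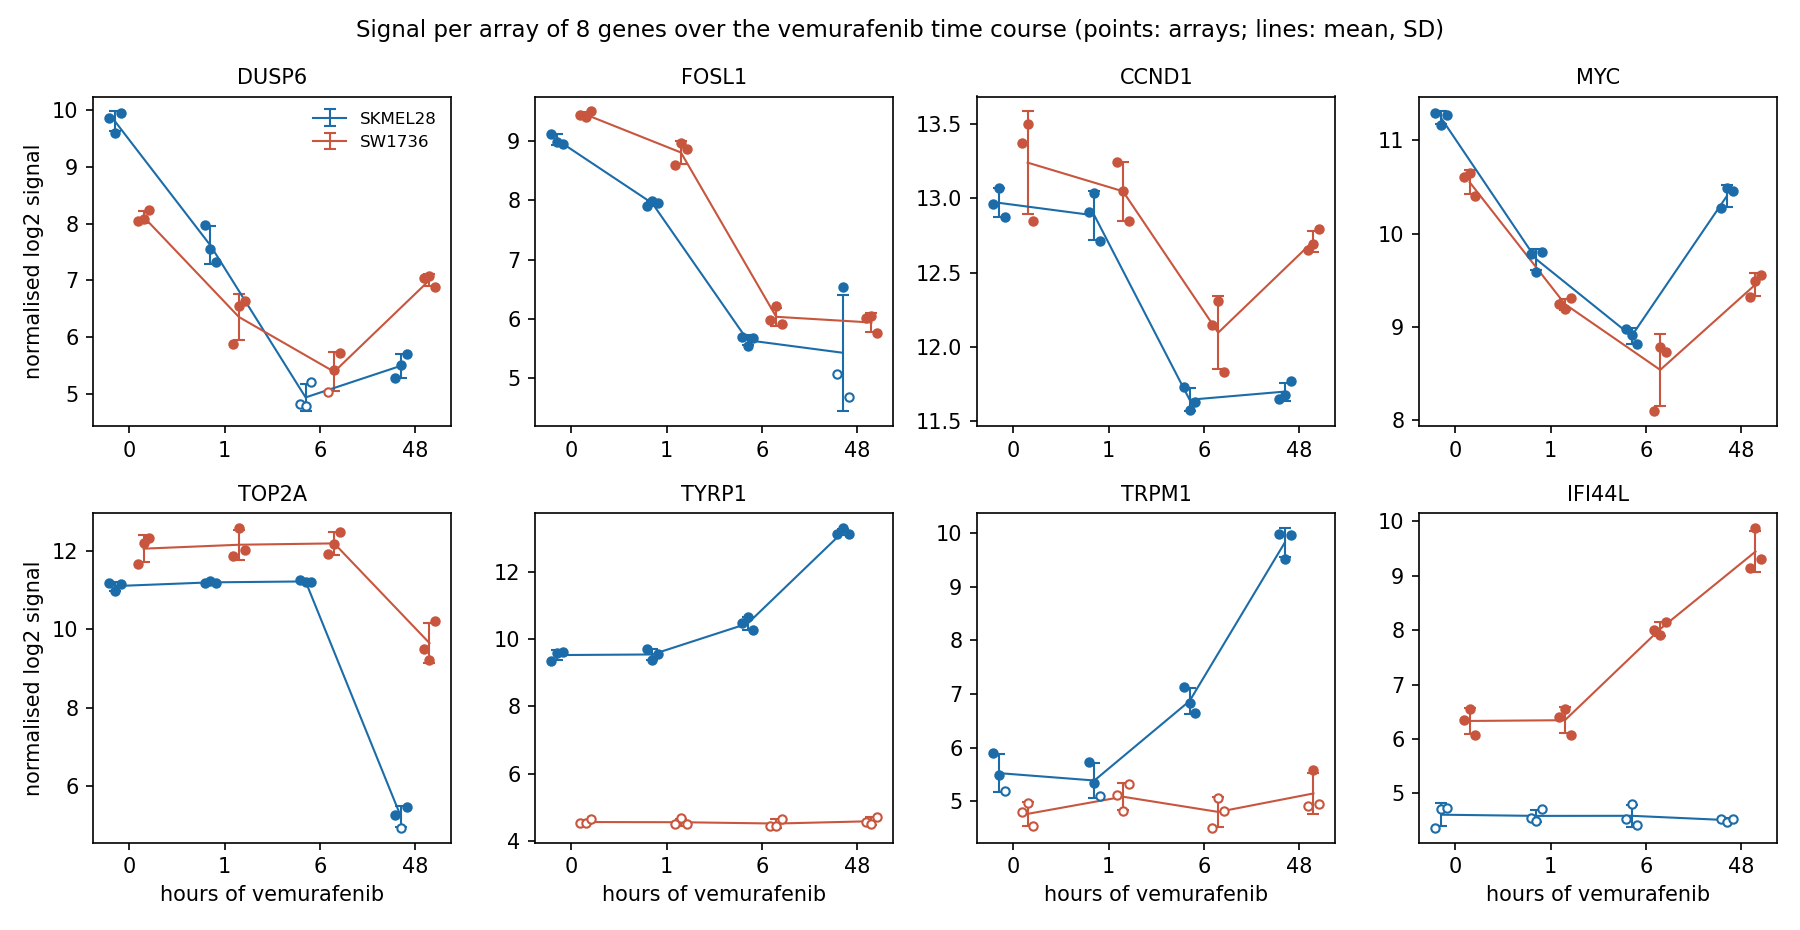
Normalised log2 signal of 8 genes (vertical axes) against hours of vemurafenib (horizontal axes) in SKMEL28 (blue) and SW1736 (red). Points are single arrays, lines join means with SD bars, and open points mark arrays on which the probe was not detected; DUSP6, FOSL1 and MYC fell in both lines by 6 h, TYRP1 and TRPM1 rose in SKMEL28 and IFI44L rose in SW1736.

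After 1 h in SKMEL28, 7 of the 19 genes that fell belonged to ERK output, among them feedback inhibitors of the RAF, MEK and ERK cascade. SPRY2, a Sprouty inhibitor of receptor signalling, changed by -2.56 ± 0.16, IER3 by -2.28 ± 0.17 and the ERK phosphatase DUSP6 by -2.19 ± 0.21. SPRY1 fell by 2.12 ± 0.18 and the AP-1 subunit FOS fell by 1.83 ± 0.18. HES1, a Notch target, fell by 1.70 ± 0.27, the growth regulator MYC by 1.52 ± 0.15, the early growth response factor EGR1 by 1.49 ± 0.27 and SPRY4 by 1.43 ± 0.22, and the microRNA gene MIR221 was at least 1.76-fold lower. ID2, an inhibitor of basic helix-loop-helix factors, rose by 1.30 ± 0.22 and EFNA1, an ephrin ligand, by 1.05 ± 0.14. ERK output genes fell in 7 of 20 and rose in none (0 higher and 10 lower adjusted over the list alone). Their median was -0.49 (camera adjusted p 1.38e-36; list p-values given with a median are camera's). Of 22 immediate early genes, 2 fell and none rose (0 higher and 6 lower adjusted over the list alone). Their median was -0.34, or -0.31 with undetected members at their bound (adjusted p 4.95e-16). Inflammatory cytokines and NF-kB targets fell in none of 18 and rose in 1 (1 higher and 4 lower adjusted over the list alone). Their median was -0.10 (adjusted p 0.00055). Of 15 Wnt and TGF-beta feedback genes, none fell and 1 rose (1 higher and 1 lower adjusted over the list alone). Their median was -0.18 (adjusted p 0.0256). In all of these lists camera pointed down. Other probes of ID2 (1.18) and SPRY4 (-1.21), detected on all 6 arrays, did not pass, nor did others of EFNA1 (0.14), SPRY1 (-0.24) and SPRY4 (0.17), detected on 0, 1 and 2 of 6. The count of changed genes was 11 without SKMEL28 0 h replicate 1 and 15 without 1 h replicate 1, and it was 14 with median scaling and 70 with array weights. ID2 did not pass without 0 h replicate 1 (1.27) or 3 (1.19), nor MIR221 without 0 h replicate 1 (-1.37). EGR1 did not pass without 0 h replicate 1 (-1.48) or 3 (-1.40), or 1 h replicate 1 (-1.52) or 3 (-1.38).

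After 1 h in SW1736, 8 of the 24 genes that fell belonged to ERK output. DUSP6 fell by 1.77 ± 0.21, MIR221 by 1.59 ± 0.24, SPRY2 by 1.43 ± 0.16, the chemokine CXCL8 by 1.36 ± 0.25, PHLDA1 by 1.34 ± 0.15 and MYC by 1.31 ± 0.15, while SPRY4 was at least 2.13-fold lower. ERK output genes fell in 8 of 20 and rose in none (0 higher and 13 lower adjusted over the list alone). Their median was -0.67 (adjusted p 1.7e-20). Of 18 inflammatory cytokines and NF-kB targets, 3 fell and none rose (0 higher and 3 lower adjusted over the list alone). Their median was 0.03 (adjusted p 0.028), and adjusted p = 0.0658 with an estimated correlation. The mean of this list was -0.22 and the test pointed down, against the sign of its median, and the call was lost with the replicate number as a block (adjusted p 0.0578). Other probes of CXCL8 (-1.65) and PHLDA1 (-0.53), detected on all 6 arrays, did not pass. Others of DUSP6 (-0.37) and SPRY4 (-0.18 and 0.03) were detected on 0, 1 and 1 of 6 and could not show a fall. MIR221 was detected on 2 of 3 1 h arrays. With SW1736 fitted alone DUSP6, SPRY2, PHLDA1 and MYC were the 4 genes that passed, and MIR221 (adjusted p 0.0868), SPRY4 (0.103) and CXCL8 (0.293) did not. The count was 12, 15 and 19 without SW1736 0 h replicate 1, 2 and 3, 19 with median scaling and 9 with array weights. CXCL8 did not pass without 0 h replicate 1 (-1.15), 0 h replicate 2 (-1.41) or 1 h replicate 3 (-1.27). It also failed with array weights (adjusted p 0.0548) and without the third SW1736 arrays (0.0675).

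The lines shared 10 of their lower genes at 1 h, namely DUSP6, SPRY1, SPRY2, SPRY4, IER3, MIR221, MYC, PDE4B, PHLDA1 and SLC2A3, where independent lists of these sizes would share 0.0333 (Fisher's exact test, p = 2.81e-24); the lines share no control arrays. They shared no higher gene. The response itself differed for 3 genes at 1 h, a count that other splits of the arrays, which kept the times of 1 line together, also reached. FOS differed by 2.00 ± 0.26 (adjusted p 0.00109), with no detection in SW1736 at 0 h or 1 h. HEY1, a Notch target, differed by 1.24 ± 0.22 and the hyaluronan synthase HAS2 by -1.28 ± 0.20; these 2 genes were chosen after their values were seen. In SW1736 these probes were detected on 0 of 3 arrays at 0 h and 1 of 3 at 1 h for HEY1 and on 3 and 1 for HAS2. Other probes of HEY1 (0.80, detected on 9 of 12 arrays) and HAS2 (0.20, 3 of 12) did not pass. Immediate early genes responded higher in SW1736 in 1 of 22 and lower in none (4 higher and 1 lower adjusted over the list alone), and 3 of the 22 were detected by no probe in SW1736 at these times. Their median was 0.22 (adjusted p 0.000175). The 3 genes became 1 without any of SKMEL28 0 h replicates 1, 2 and 3 and 1 h replicate 3, or without SW1736 0 h replicate 1 or 1 h replicate 1. There were 2 without SKMEL28 1 h replicate 1 or 2 and 5 without SW1736 1 h replicate 3. Leaving out 1 array, HEY1 passed only without SW1736 0 h replicate 3 or 1 h replicate 2, at 1.09 to 1.28 without each of the others. HAS2 did not pass without SKMEL28 0 h replicate 1, 2 or 3 or 1 h replicate 2 or 3 (-1.30 to -1.22). Nor did it without SW1736 0 h or 1 h replicate 1 (-1.25 and -1.27). Median scaling (adjusted p 0.162 and 0.125) and the replicate number as a block (0.0848 and 0.0785) ended the calls of HEY1 and HAS2. The trended robust prior ended that of HEY1 (0.0512) and leaving out the third SW1736 arrays that of HAS2 (0.0827).

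After 6 h in SKMEL28 the largest falls included feedback inhibitors of the ERK cascade. SPRY2, detected on 2 of 3 arrays at 6 h, fell by 5.40 ± 0.16 and SPRY1 fell by 3.59 ± 0.18. DUSP6 was at least 22.4-fold and SPRY4 at least 17.6-fold lower, and neither of these was detected on the 6 h arrays. UCN2, a urocortin peptide, fell by 3.53 ± 0.22, the AP-1 subunit FOSL1 by 3.39 ± 0.27, CXCL8 by 3.25 ± 0.25, ST8SIA1, which makes the ganglioside GD3, by 3.17 ± 0.18 and the stress cytokine GDF15 by 3.10 ± 0.14. CCND1, the cyclin of G1 entry, fell by 1.33 ± 0.16 and EGR1 by 2.66 ± 0.27. ID2 rose by 2.64 ± 0.22, OMG, a myelin glycoprotein, by 2.18 ± 0.19, DIPK1C by 1.98 ± 0.19, the p53 target TP53INP1 by 1.94 ± 0.17 and CHSY3, a chondroitin synthase, by 1.81 ± 0.17; PRUNE2 was at least 8.26-fold and the BMP inhibitor SMAD6 at least 3.64-fold higher.

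By list, ERK output and growth genes fell in SKMEL28 at 6 h and brakes on division and pigment genes rose. Of 20 ERK output genes, 16 fell and none rose (0 higher and 18 lower adjusted over the list alone). The ERK output median was -1.74 (adjusted p 1.32e-41). Immediate early genes fell in 7 of 22 and rose in none (1 higher and 9 lower adjusted over the list alone), such as FOS (-2.27 ± 0.18). Their median was -0.48, or -0.47 with bounds (adjusted p 4.73e-09). Of 25 ribosome biogenesis genes, 13 fell and none rose (0 higher and 20 lower adjusted over the list alone), such as PPAN (-1.69 ± 0.22). Their median was -0.64 (adjusted p 2.61e-15). Glycolysis and hypoxia genes fell in 6 of 22 and rose in none (0 higher and 6 lower adjusted over the list alone), such as the glucose transporters SLC2A3 (-2.51 ± 0.15), SLC2A1 (-1.18 ± 0.16) and the regulatory enzyme PFKFB4 (-1.46 ± 0.19). Their median was -0.10 (adjusted p 0.000103). Of 18 inflammatory cytokines and NF-kB targets, 6 fell and 1 rose (1 higher and 6 lower adjusted over the list alone), such as the chemokine CCL20 (-2.84 ± 0.15). Their median was -0.42 (adjusted p 9.44e-07). IL1B, an inflammatory cytokine, was at least 3.64-fold lower. FOXO targets and PI3K feedback genes rose in 7 of 18 and fell in 2 (9 higher and 3 lower adjusted over the list alone), such as the ubiquitin ligase TRIM63 (1.28 ± 0.15). Their median was 0.53 (adjusted p 0.000138). Of 17 cell cycle brakes, 6 rose and 1 fell (9 higher and 2 lower adjusted over the list alone), such as the MYC antagonist MXD4 (1.32 ± 0.25). Their median was 0.40 (adjusted p 0.000473). Melanocyte and pigment genes rose in 6 of 21 and fell in 2 (10 higher and 3 lower adjusted over the list alone), such as the channel TRPM1 (1.35 ± 0.23), the melanosomal transporter OCA2 (0.95 ± 0.14) and the pigment enzyme TYRP1 (0.94 ± 0.14). Their median was 0.20 (adjusted p 0.000964). Of 15 Wnt and TGF-beta feedback genes, 3 fell and 2 rose (2 higher and 6 lower adjusted over the list alone), such as the Wnt inhibitor DKK1 (-2.69 ± 0.15) and LEF1 (-1.82 ± 0.15). Their median was -0.28 (adjusted p 0.0322). It had an adjusted p = 0.049 with an estimated correlation, and the call was lost with median scaling (adjusted p 0.169) and with the stricter filter (0.0777). FOS and CCL20 were detected on 2 of 3 arrays at 6 h and TRPM1 on 2 of 3 at 0 h. Other probes of SPRY1 (-0.23), SPRY4 (-0.10) and DKK1 (-0.05), detected on 2, 0 and 0 of 6 arrays, could not show a fall. SKMEL28 had 1832 changed genes at 6 h when fitted alone and 2053 with array weights.

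After 6 h in SW1736, ERK output genes fell, and genes of amino acid stress and of the interferon response rose. FOSL1 fell by 3.42 ± 0.27, the G-protein regulator RGS4 by 2.92 ± 0.26, the ERK-driven transcription factor ETV5 by 2.83 ± 0.14 and the YAP targets CCN1 and CCN2 by 2.75 ± 0.19 and 2.71 ± 0.14. DUSP6 changed by -2.73 ± 0.21, EMP1 by -2.62 ± 0.16, SPRY2 by -2.54 ± 0.16 and CCND1 by -1.14 ± 0.16; CNIH3 was at least 3.01-fold and SPRY4, not detected by this probe at 6 h, at least 2.21-fold lower. DUSP6 and RGS4 were detected on 2 of 3 arrays at 6 h. LMO1, a transcriptional cofactor, rose by 2.97 ± 0.25, CTH, which makes cysteine, by 2.55 ± 0.21, the stress factor NUPR1 by 2.42 ± 0.26, NNMT by 2.33 ± 0.22 and DDIT4, an inhibitor of mTORC1, by 2.15 ± 0.16; TENT5A was at least 2.95-fold higher.

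By list, ERK output, DNA replication and ribosome genes fell in SW1736 at 6 h. ERK output genes fell in 19 of 20 and rose in none (1 higher and 19 lower adjusted over the list alone). The ERK output median was -1.84, or -1.72 with bounds (adjusted p 5.12e-35). Of 22 amino acid and ER stress response genes, 12 rose and none fell (17 higher and 1 lower adjusted over the list alone), such as PCK2 (1.17 ± 0.18), the asparagine synthetase ASNS (1.17 ± 0.15) and the stress factor DDIT3 (1.16 ± 0.24). Their median was 0.67, or 0.65 with bounds (adjusted p 1.56e-12). Interferon response genes rose in 13 of 22 and fell in none (15 higher and 0 lower adjusted over the list alone), such as IFI44L (1.69 ± 0.18), the immunoproteasome subunit PSMB9 (1.16 ± 0.20) and the membrane protein IFITM1 (1.15 ± 0.17). Their median was 0.72 (adjusted p 3.13e-13). Of 17 cell cycle brakes, 10 rose and 1 fell (13 higher and 1 lower adjusted over the list alone), such as GAS1 (1.67 ± 0.19). Their median was 0.68 (adjusted p 2.09e-08). FOXO targets and PI3K feedback genes rose in 6 of 18 and fell in 1 (7 higher and 1 lower adjusted over the list alone), such as the cyclin CCNG2 (1.53 ± 0.20). Their median was 0.22 (adjusted p 0.00365). Of 30 S phase and E2F targets, 13 fell and none rose (0 higher and 18 lower adjusted over the list alone), such as the ribonucleotide reductase subunit RRM2 (-1.07 ± 0.22). Their median was -0.45, or -0.42 with bounds (adjusted p 2.06e-10). Ribosome biogenesis genes fell in 15 of 25 and rose in none (0 higher and 18 lower adjusted over the list alone), such as MRTO4 (-1.42 ± 0.21). Their median was -0.74 (adjusted p 5.23e-15). Of 22 glycolysis and hypoxia genes, 5 fell and none rose (0 higher and 5 lower adjusted over the list alone), such as the hexokinase HK2 (-1.88 ± 0.18) and SLC2A3 (-1.33 ± 0.15). Their median was -0.16 (adjusted p 0.0169). Matrix, adhesion and EMT genes fell in 6 of 24 and rose in 2 (3 higher and 6 lower adjusted over the list alone), with THBS1 (-2.08 ± 0.17) and the urokinase PLAU (-1.19 ± 0.17) among the lower ones. Their median was -0.14 (adjusted p 0.0151). Other probes of CCNG2 (0.75), HK2 (-0.60) and PSMB9 (0.06), detected on all 6 arrays, did not pass. Others of DUSP6 (-0.37), SPRY4 (-0.23 and 0.07) and CCNG2 (0.36), which did not pass either, were detected on 0, 1, 2 and 1 of 6. EGR1 changed by -0.95 ± 0.27 (adjusted p 0.027). Its call was lost without SW1736 0 h replicate 1 (-0.93), 0 h replicate 2 (-0.82), 6 h replicate 1 (-0.87) or 6 h replicate 2 (-0.76), with the line alone (adjusted p 0.116) and with array weights (0.0541). Array weights gave 618 changed genes.

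The lines shared 162 lower genes at 6 h where independent lists would share 27.0 (Fisher's exact test, p = 1.6e-84) and 59 higher genes where they would share 14.5 (p = 1.22e-20). Across genes, which are not independent replicates, the changes of the lines correlated with r = 0.111 at 1 h, 0.284 at 6 h and 0.527 at 48 h (Spearman 0.083, 0.256 and 0.466). The response differed for 581 genes at 6 h (314 higher and 267 lower in SW1736), 369 with median scaling. The lipid phosphatase PLPP3 differed by 3.68 ± 0.26, UCN2 by 3.24 ± 0.31, NNMT by 2.93 ± 0.31, the transcription factor CEBPB by 2.74 ± 0.20, ISM1 by -2.65 ± 0.29 and EMP1 by -2.55 ± 0.22, and SPRY2 (2.86 ± 0.23) and EGR1 (1.71 ± 0.38) fell further in SKMEL28. FOS (2.19 ± 0.26) differed too, with no detection in SW1736. SPRY4 (2.82 ± 0.31) and DUSP6 (2.14 ± 0.29) differed as fitted, but at 6 h this SPRY4 probe was detected in neither line (another on 1 SW1736 array) and DUSP6 on 0 of 3 arrays in SKMEL28 and 2 of 3 in SW1736. With this probe at background in both lines, the value of SPRY4 is close to its difference between untreated lines with the sign turned (-2.95). Of 22 amino acid and ER stress response genes, 7 responded higher in SW1736 and none lower (10 higher and 0 lower adjusted over the list alone), such as DDIT4 (2.46 ± 0.23) and the kinase-like TRIB3 (2.03 ± 0.25). Their median was 0.57 (adjusted p 5.67e-09). Interferon response genes responded higher in SW1736 in 3 of 22 and lower in none (8 higher and 0 lower adjusted over the list alone), such as IFI44L (1.71 ± 0.26) and IFITM1 (1.32 ± 0.24), both without detection in SKMEL28 at 6 h. Their median was 0.64 (adjusted p 4e-09). Of 30 S phase and E2F targets, 3 responded lower in SW1736 and none higher (0 higher and 5 lower adjusted over the list alone). Their median was -0.43 (adjusted p 1.79e-07). ERK output genes responded higher in SW1736 in 6 of 20 and lower in 3 (6 higher and 3 lower adjusted over the list alone). Their median was 0.21 (adjusted p 0.0203). Of 21 melanocyte and pigment genes, 5 responded lower in SW1736 and 2 higher (2 higher and 8 lower adjusted over the list alone), and 10 of them were detected by no probe in SW1736 at 0 h or 6 h. Their median was -0.22 (adjusted p 0.006). That call was lost with median scaling (adjusted p 0.306). Immediate early genes responded higher in SW1736 in 4 of 22 and lower in 2 (7 higher and 2 lower adjusted over the list alone), such as RHOB (2.08 ± 0.26). Their median was 0.48 (adjusted p 0.00903), and adjusted p = 0.129 with an estimated correlation. Of 18 inflammatory cytokines and NF-kB targets, 4 responded higher in SW1736 and 2 lower (7 higher and 2 lower adjusted over the list alone), such as CXCL8 (2.28 ± 0.35) and CCL20 (2.69 ± 0.22), the latter without detection in SW1736. Their median was 0.52 (adjusted p 0.014), and adjusted p = 0.0517 with an estimated correlation. This last call was also lost without background correction (adjusted p 0.0867), with the authors' values (0.0866) and without the third SW1736 arrays (0.0901). Other probes of CXCL8 (1.30, detected on all 12 arrays), IFI44L (0.93, 7 of 12), ISM1 (0.18, 3 of 12) and SPRY4 (0.17, 2 of 12) did not pass.

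**Figure D2:**
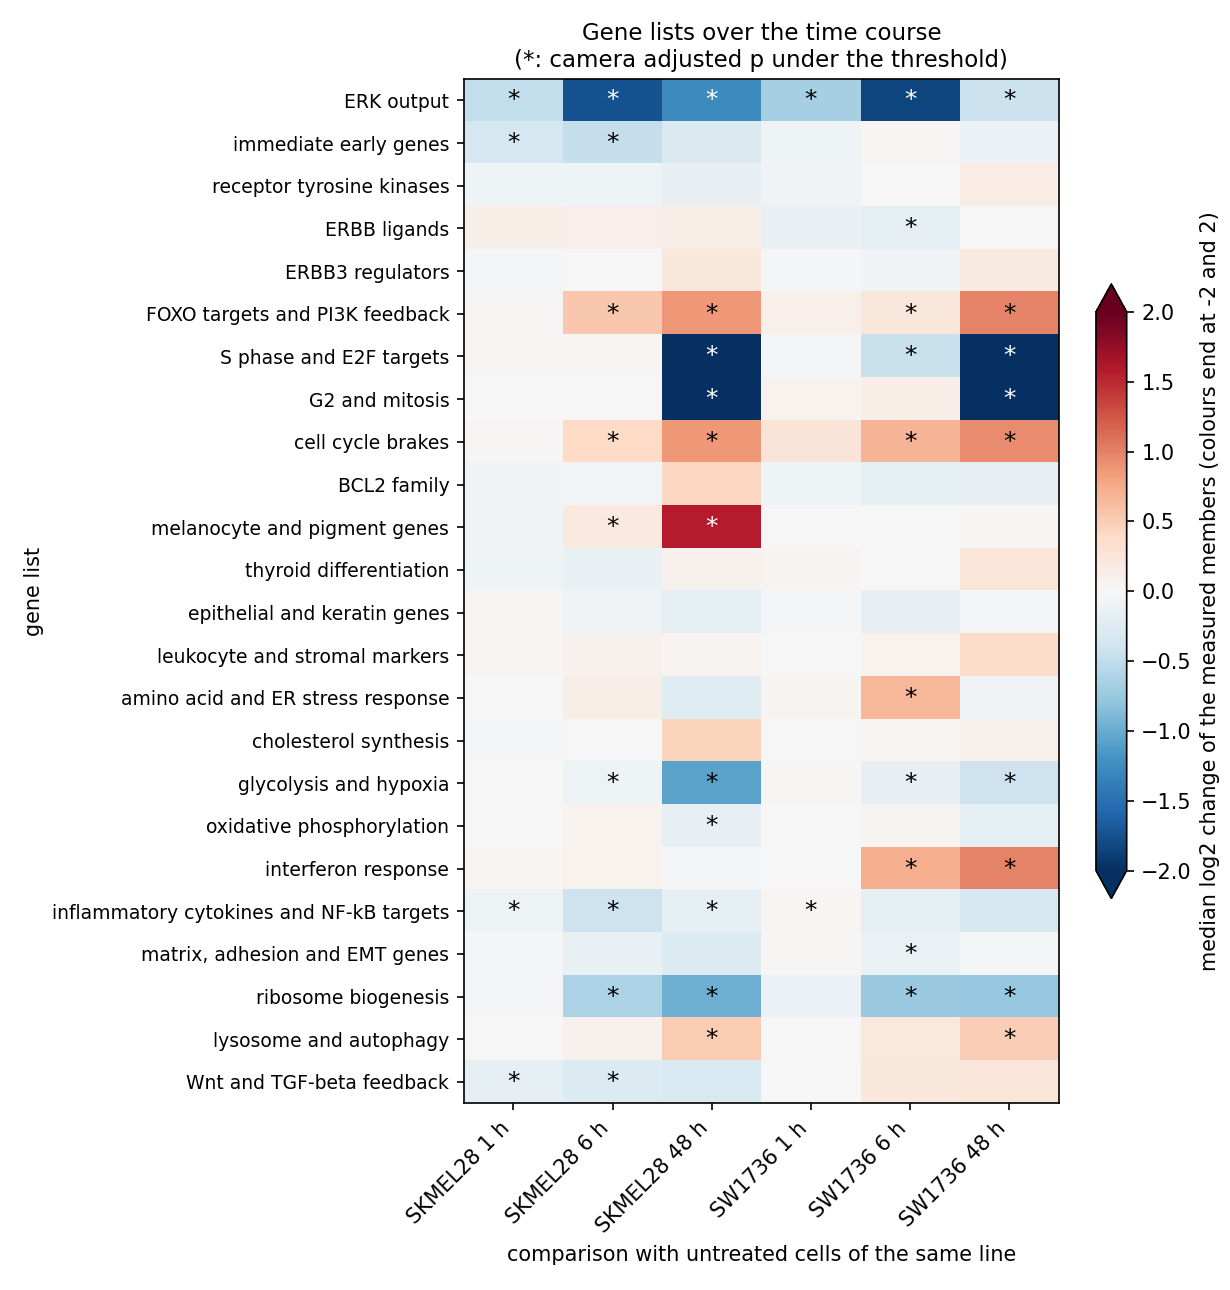
Median log2 change (colour, ending at -2 and 2) of the measured members of 24 gene lists (vertical axis) in the 6 comparisons with untreated cells (horizontal axis). Stars mark lists with a camera adjusted p under 0.05; ERK output carries a star in all 6 columns, G2 and mitosis at 48 h in both lines, and at 6 h and 48 h melanocyte and pigment genes in SKMEL28 and interferon response in SW1736.

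After 48 h in SKMEL28 cell division genes had fallen and pigment cell genes had risen. TOP2A, the topoisomerase of dividing cells, fell by 5.90 ± 0.23 to about background (detected on 2 of 3 arrays at 48 h), the mitotic ubiquitin enzyme UBE2C by 5.70 ± 0.15, the anaphase activator CDC20 by 5.50 ± 0.18 and the condensin subunit NCAPG by 5.43 ± 0.14, and the centromere genes HJURP and BUB1 were at least 34.5-fold and 32.5-fold lower. SERPINF1, the secreted factor PEDF, rose by 4.52 ± 0.17, TRPM1 by 4.30 ± 0.23, IL17D by 3.98 ± 0.19, the melanocyte cofactor CITED1 by 3.77 ± 0.12, the prostaglandin dehydrogenase HPGD by 3.69 ± 0.17 and TYRP1 by 3.66 ± 0.14, and SMAD6 was at least 10.6-fold higher. SERPINF1 and TRPM1 were detected on 2 of 3 untreated arrays. DUSP6 (-4.31 ± 0.21), SPRY4 (-3.33 ± 0.22), EGR1 (-2.24 ± 0.27) and CCND1 (-1.27 ± 0.16) stayed below untreated cells, and MITF, the master regulator of melanocytes, rose by 0.86 ± 0.21.

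By list, genes of cell division, ERK output, glycolysis and ribosome biogenesis fell in SKMEL28 at 48 h and pigment genes rose. G2 and mitosis genes fell in 30 of 30 and rose in none (0 higher and 30 lower adjusted over the list alone). Their median was -4.13, or -4.09 with bounds (adjusted p 1.2e-41). Of 30 S phase and E2F targets, 28 fell and none rose (0 higher and 28 lower adjusted over the list alone), such as the nucleotide enzyme TYMS (-4.81 ± 0.16) and the replication factor CDC45 (-4.75 ± 0.15). Their median was -2.29, or -2.19 with bounds (adjusted p 5.48e-28). ERK output genes fell in 17 of 20 and rose in 1 (2 higher and 17 lower adjusted over the list alone), such as FOSL1 (-3.60 ± 0.27) and ETV4 (-3.47 ± 0.21), each detected on 1 of 3 arrays at 48 h. The ERK output median was -1.27 (adjusted p 2.14e-09). Of 21 melanocyte and pigment genes, 15 rose and 2 fell (16 higher and 2 lower adjusted over the list alone), such as TSPAN10 (3.11 ± 0.27). Their median was 1.57 (adjusted p 5.48e-08). Cell cycle brakes rose in 12 of 17 and fell in 2 (12 higher and 2 lower adjusted over the list alone), such as MXD4 (3.29 ± 0.25). Their median was 0.87 (adjusted p 0.000278). Of 18 FOXO targets and PI3K feedback genes, 9 rose and 2 fell (9 higher and 2 lower adjusted over the list alone), such as TRIM63 (2.74 ± 0.15). Their median was 0.87 (adjusted p 0.000346). Lysosome and autophagy genes rose in 11 of 22 and fell in 3 (12 higher and 3 lower adjusted over the list alone), such as GABARAPL1 (1.85 ± 0.30). Their median was 0.51 (adjusted p 0.0134). This list had an adjusted p = 0.049 with an estimated correlation. Of 22 glycolysis and hypoxia genes, 17 fell and none rose (0 higher and 18 lower adjusted over the list alone), such as PFKFB4 (-2.55 ± 0.19). Their median was -1.06 (adjusted p 3.71e-10). Ribosome biogenesis genes fell in 20 of 25 and rose in none (0 higher and 21 lower adjusted over the list alone), such as NOLC1 (-2.05 ± 0.20). Their median was -0.98 (adjusted p 3.95e-10). Of 21 oxidative phosphorylation genes, 10 fell and none rose (0 higher and 10 lower adjusted over the list alone), such as the ATP synthase subunit ATP5MC1 (-1.57 ± 0.16). Their median was -0.17 (adjusted p 0.0322), and adjusted p = 0.0594 with an estimated correlation. Inflammatory cytokines and NF-kB targets fell in 7 of 18 and rose in 1 (1 higher and 7 lower adjusted over the list alone), such as CXCL8, which was not detected by this probe at 48 h and was at least 16.8-fold lower. Their median was -0.18 (adjusted p 0.0247), and adjusted p = 0.0594 with an estimated correlation. SPRY4 had another probe (-0.22), detected on 0 of 6 arrays, that could not show a fall.

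After 48 h in SW1736 interferon response genes had risen and cell division genes had fallen. SLPI, a secreted protease inhibitor, rose by 5.63 ± 0.21, about 49.4-fold, the complement factor CFB by 5.24 ± 0.18, the chloride channel protein CLIC3 by 4.93 ± 0.20, the potassium channel KCNJ16 by 4.89 ± 0.18, RARRES1 by 4.84 ± 0.31 and the proteoglycan BGN by 4.36 ± 0.18; the lysosomal sulfatase SGSH was at least 6.19-fold higher. DEPDC1 fell by 3.70 ± 0.24, the spindle protein DLGAP5 by 3.66 ± 0.14, and the kinesin KIF2C fell by 3.59 ± 0.15. The thymidine kinase TK1 fell by 3.55 ± 0.22 and FOSL1 fell by 3.52 ± 0.27. The noncoding RNA MANCR was at least 18.1-fold and the chromatin protein HMGA2 at least 3.05-fold lower. CLIC3 was detected on 2 of 3 untreated arrays and DEPDC1 on 2 of 3 at 48 h. DUSP6 (-1.12 ± 0.21) and EGR1 (-1.02 ± 0.27) stayed below untreated cells, whereas SPRY4 did not differ past the test (-0.22 ± 0.22).

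By list, genes of cell division fell in SW1736 at 48 h and interferon, FOXO and lysosome genes rose. Of 30 G2 and mitosis genes, 30 fell and none rose (0 higher and 30 lower adjusted over the list alone), such as the kinase AURKA (-3.40 ± 0.18). Their median was -2.85 (adjusted p 2.14e-41). S phase and E2F targets fell in 28 of 30 and rose in none (0 higher and 28 lower adjusted over the list alone), such as RRM2 (-3.31 ± 0.22). Their median was -1.996 (adjusted p 6.05e-29). Of 22 interferon response genes, 18 rose and 1 fell (18 higher and 1 lower adjusted over the list alone), such as IFI44L (3.12 ± 0.18), IFITM1 (2.35 ± 0.17), IFI27 (2.00 ± 0.25; detected on 1 of 3 untreated arrays) and IFI6 (1.36 ± 0.18). Their median was 0.99 (adjusted p 1.29e-07). Cell cycle brakes rose in 14 of 17 and fell in 2 (14 higher and 2 lower adjusted over the list alone), such as MXD4 (2.63 ± 0.25). Their median was 0.94 (adjusted p 1.26e-05). Of 18 FOXO targets and PI3K feedback genes, 10 rose and none fell (11 higher and 0 lower adjusted over the list alone), such as KLHL24 (2.68 ± 0.15). Their median was 0.99 (adjusted p 1.75e-06). Lysosome and autophagy genes rose in 11 of 22 and fell in none (12 higher and 1 lower adjusted over the list alone), such as the protease CTSD (1.97 ± 0.17). Their median was 0.49 (adjusted p 0.000249). Of 20 ERK output genes, 9 fell and 3 rose (4 higher and 10 lower adjusted over the list alone). The higher ones, named after their values were seen, were EPHA4 (1.66 ± 0.23), SPRY1 (1.03 ± 0.18) and DUSP5 (0.94 ± 0.20). The ERK output median was -0.42 (adjusted p 0.0272). Ribosome biogenesis genes fell in 19 of 25 and rose in none (0 higher and 21 lower adjusted over the list alone), such as MRTO4 (-1.61 ± 0.21). Their median was -0.76 (adjusted p 1.55e-08). Of 22 glycolysis and hypoxia genes, 10 fell and 1 rose (1 higher and 10 lower adjusted over the list alone), such as the enolase ENO2 (-1.28 ± 0.24). Their median was -0.42 (adjusted p 0.0138). Another KCNJ16 probe (-0.02, detected on 4 of 6 arrays) did not pass, and others of DUSP6 (-0.17), HMGA2 (-0.36) and SPRY1 (0.21), detected on 0 of 6, could not show a change. CCND1 changed by -0.53 ± 0.16 (adjusted p 0.0138). That call was lost without SW1736 0 h replicate 1 (-0.46) or 0 h replicate 2 (-0.40) and with the line alone (adjusted p 0.0762).

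At 48 h the lines shared 1152 higher genes where independent lists would share 498.5 (Fisher's exact test, p = 1.94e-246) and 1245 lower genes where they would share 415.6, while 106 and 169 genes moved in opposite directions against 442.0 and 468.8. The response differed for 2881 genes (1574 higher and 1307 lower in SW1736). The matrix protein TNC differed by 4.79 ± 0.20, the integrin ITGB3 by 4.66 ± 0.25 and PLPP3 by 4.65 ± 0.26, and SH3PXD2A by -3.38 ± 0.27, JUN by -3.18 ± 0.36 and HES6 by -3.11 ± 0.21. The falls of ERK output, cell division and glycolysis genes were smaller in SW1736. ERK output genes responded higher in SW1736 in 12 of 20 and lower in 1 (13 higher and 2 lower adjusted over the list alone), such as DUSP6 (3.20 ± 0.29) and SPRY4 (3.11 ± 0.31). Their median was 0.85 (adjusted p 1.42e-05). Of 30 G2 and mitosis genes, 20 responded higher in SW1736 and none lower (20 higher and 0 lower adjusted over the list alone), such as TOP2A (3.48 ± 0.32; near background in SKMEL28 at 48 h). Their median was 1.18 (adjusted p 4.73e-12). Glycolysis and hypoxia genes responded higher in SW1736 in 11 of 22 and lower in none (13 higher and 0 lower adjusted over the list alone), such as PFKFB4 (2.16 ± 0.27). Their median was 0.61 (adjusted p 4.34e-06). Of 30 S phase and E2F targets, 10 responded higher in SW1736 and 1 lower (11 higher and 2 lower adjusted over the list alone), such as TYMS (2.09 ± 0.22). Their median was 0.53 (adjusted p 0.000372). That call was lost without background correction and with the authors' values (adjusted p 0.137 in each). Melanocyte and pigment genes responded lower in SW1736 in 14 of 21 and higher in 3 (3 higher and 15 lower adjusted over the list alone), such as TRPM1 (-3.92 ± 0.32) and TYRP1 (-3.63 ± 0.19). In SW1736 at 0 h and 48 h TYRP1 was not detected, TRPM1 was detected on 1 of 6 arrays and 8 of the 21 were detected by no probe, so these differences are close to the SKMEL28 changes. The list median was -1.53 (adjusted p 2.49e-09). Of 22 interferon response genes, 13 responded higher in SW1736 and none lower (18 higher and 0 lower adjusted over the list alone), such as IFI44L (3.21 ± 0.26), IFITM1 (2.71 ± 0.24) and ISG15 (2.43 ± 0.21), the first 2 of them without detection in SKMEL28 at 48 h. Their median was 0.90 (adjusted p 9.95e-08). Cholesterol synthesis genes responded lower in SW1736 in 2 of 16 and higher in none (0 higher and 2 lower adjusted over the list alone), such as IDI1 (-1.46 ± 0.35). Their median was -0.54 (adjusted p 0.0361), and adjusted p = 0.215 with an estimated correlation. It was also lost with the stricter filter (adjusted p 0.057). MITF (-0.97 ± 0.30, adjusted p 0.021) did not pass without SKMEL28 48 h replicate 3 (-0.88) or SW1736 48 h replicate 2 (-0.82). CCND1 (0.74 ± 0.23, adjusted p 0.0224) did not pass without SKMEL28 0 h replicate 2 (0.69) or SW1736 0 h replicate 3 (0.55). EGR1 (1.22 ± 0.38, adjusted p 0.0238) did not pass without SKMEL28 0 h replicate 3 (1.13) or 48 h replicate 3 (1.18), or SW1736 0 h replicate 3 (1.07) or 48 h replicate 3 (1.04). With median scaling MITF (adjusted p 0.0977) and CCND1 (0.0716) did not pass, nor did CCND1 without the third SW1736 arrays (0.057). SPRY4 had another probe that did not pass (0.46, detected on 3 of 12 arrays).

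From 6 h to 48 h, 4509 genes changed in SKMEL28 (2444 higher, 2065 lower) and 3768 in SW1736 (2041 higher, 1727 lower; 2462 with the line alone), and ERK output rose in both. In SKMEL28 SPRY2 rose by 3.10 ± 0.16, SPRY1 by 2.05 ± 0.18 and IER3 by 1.90 ± 0.17; in SW1736 SPRY1 rose by 3.39 ± 0.18, SPRY2 by 2.91 ± 0.16, ETV5 by 2.25 ± 0.14, DUSP5 by 1.79 ± 0.20 and DUSP6 by 1.62 ± 0.21. Of 20 ERK output genes, 11 rose and 2 fell in SKMEL28 (11 higher and 2 lower adjusted over the list alone). ERK output there had a median of 0.55, or 0.43 with bounds (adjusted p 0.00337). In SW1736, 16 of the 20 rose and 1 fell (16 higher and 1 lower adjusted over the list alone). Of the 16 genes of this list that had fallen at 6 h in SKMEL28, 10 rose from 6 h to 48 h. Of the 19 in SW1736, 15 did, and 1 and 2 of these ended above untreated cells. Both changes use the same 6 h arrays, so noise there favours a return in genes picked by their fall at 6 h. In SW1736 the median was 1.28 (adjusted p 3.82e-10). The largest other rises were SERPINF1 (3.82 ± 0.17), the AP-1 subunit JUN (3.34 ± 0.26) and GDF11 (3.13 ± 0.19) in SKMEL28 and SLPI (4.63 ± 0.21), KCNJ16 (3.96 ± 0.18), CLIC3 (3.68 ± 0.20) and RGS4 (3.66 ± 0.26) in SW1736. TOP2A (-6.02 ± 0.23) and UBE2C (-5.49 ± 0.15) fell in SKMEL28 and KIF20A (-4.04 ± 0.16) and APOBEC3B (-3.81 ± 0.23) in SW1736. All 30 G2 and mitosis genes fell in each line (30 in each adjusted over the list alone). Their medians were -3.95 in SKMEL28, or -3.80 with bounds, and -2.79 in SW1736 (camera adjusted p 1.03e-51 and 6.41e-52). S phase and E2F targets fell in 27 of 30 in SKMEL28 and 25 in SW1736 (28 and 25 adjusted over the list alone). Their medians were -2.34, or -2.30 with bounds, and -1.40 (adjusted p 2.49e-33 and 2.38e-25). SPRY2 and JUN in SKMEL28 and RGS4 and DUSP6 in SW1736 were detected on 2 of 3 arrays at 6 h, and TOP2A in SKMEL28 and APOBEC3B in SW1736 on 2 of 3 at 48 h. Other probes of SPRY1 (-0.08 in SKMEL28, -0.09 in SW1736), KCNJ16 (0.24) and DUSP6 (0.20 in SW1736) did not pass, detected on 1, 0, 2 and 0 of 6 arrays.

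Further lists moved from 6 h to 48 h, first in SKMEL28. Of 18 FOXO targets and PI3K feedback genes, 10 rose and 1 fell (10 higher and 1 lower adjusted over the list alone). Their median was 0.64 (adjusted p 0.00367). Lysosome and autophagy genes rose in 10 of 22 and fell in 2 (11 higher and 3 lower adjusted over the list alone). Their median was 0.41 (adjusted p 0.016), and adjusted p = 0.0501 with an estimated correlation. Of 21 melanocyte and pigment genes, 15 rose and 1 fell (16 higher and 1 lower adjusted over the list alone). Their median was 1.33 (adjusted p 3.62e-08). Cell cycle brakes rose in 9 of 17 and fell in 1 (10 higher and 2 lower adjusted over the list alone). Their median was 0.55 (adjusted p 0.0147). Of 16 cholesterol synthesis genes, 9 rose and 1 fell (11 higher and 1 lower adjusted over the list alone), such as HMGCS1 (1.33 ± 0.22). Their median was 0.57 (adjusted p 0.0237), and adjusted p = 0.155 with an estimated correlation. Glycolysis and hypoxia genes fell in 14 of 22 and rose in 1 (1 higher and 14 lower adjusted over the list alone). Their median was -0.92 (adjusted p 1.25e-06). Of 21 oxidative phosphorylation genes, 10 fell and 1 rose (1 higher and 11 lower adjusted over the list alone). Their median was -0.34 (adjusted p 0.00404). Ribosome biogenesis genes fell in 12 of 25 and rose in 1 (1 higher and 12 lower adjusted over the list alone). Their median was -0.41 (adjusted p 0.00381). In SW1736, of the 12 amino acid and ER stress response genes that had risen at 6 h, 10 fell from 6 h to 48 h, and 2 of these were then below untreated cells. Over the whole list 4 genes were higher and 7 lower than untreated at 48 h (5 and 8 adjusted over the list alone; camera adjusted p 0.327), such as SLC7A5 (-1.50 ± 0.16) and PSAT1 (-1.05 ± 0.14), named after their values were seen. From 6 h to 48 h 14 of the 22 genes fell and 1 rose (2 higher and 16 lower adjusted over the list alone), such as ASNS (-2.17 ± 0.15), the serine enzyme PSAT1 (-2.07 ± 0.14) and SLC7A5 (-1.86 ± 0.16). Their median was -0.71, or -0.60 with bounds (adjusted p 2.13e-08). FOXO targets and PI3K feedback genes rose in 9 of 18 and fell in none (9 higher and 0 lower adjusted over the list alone). Their median was 0.51 (adjusted p 6.72e-05). Of 22 lysosome and autophagy genes, 10 rose and 1 fell (11 higher and 1 lower adjusted over the list alone). Their median was 0.42 (adjusted p 0.0021). ERBB3 regulators rose in 8 of 16 and fell in 1 (8 higher and 1 lower adjusted over the list alone), such as LRIG1 (1.55 ± 0.20), which lowers ERBB receptors, and GATA3 (1.54 ± 0.25; detected on 2 of 3 arrays at 6 h). Their median was 0.44 (adjusted p 0.0186). Of 21 oxidative phosphorylation genes, 6 fell and 1 rose (1 higher and 6 lower adjusted over the list alone). Their median was -0.25 (adjusted p 0.0366), and adjusted p = 0.0623 with an estimated correlation. Matrix, adhesion and EMT genes rose in 10 of 24 and fell in 1 (10 higher and 1 lower adjusted over the list alone), such as SNAI2 (1.16 ± 0.24). Their median was 0.24 (adjusted p 0.0366). Median scaling ended the calls of oxidative phosphorylation (adjusted p 0.0619) and of matrix, adhesion and EMT genes (0.0611) in SW1736, and the stricter filter the latter (0.0567).

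The change from 6 h to 48 h differed between the lines for 2491 genes (1332 higher and 1159 lower in SW1736), a count that 8 of 100 splits of the arrays reached, the real one included; the 7 others kept the times of 1 line together, and splits that kept neither reached at most 1 gene. TMEM158 differed by 4.47 ± 0.27, TNC by 4.46 ± 0.20 and the interferon-induced GTPase GBP2 by 3.57 ± 0.30, and JUN by -3.04 ± 0.36 and HES6 by -2.84 ± 0.21. ERK output rose further in SW1736 and cell division genes fell less there. Of 20 ERK output genes, 8 responded higher in SW1736 and 1 lower (9 higher and 2 lower adjusted over the list alone), such as ETV4 (2.17 ± 0.30), ETV5 (1.70 ± 0.20) and DUSP6 (1.06 ± 0.29). In SKMEL28 DUSP6 was not detected at 6 h and ETV4 was detected on 1 of 3 arrays at 48 h. For ERK output the median was 0.57 (adjusted p 0.00411). S phase and E2F targets responded higher in SW1736 in 20 of 30 and lower in none (23 higher and 0 lower adjusted over the list alone). Their median was 0.93 (adjusted p 4.76e-12). Of 30 G2 and mitosis genes, 20 responded higher in SW1736 and 1 lower (22 higher and 2 lower adjusted over the list alone). Their median was 0.97 (adjusted p 5.33e-11). Glycolysis and hypoxia genes responded higher in SW1736 in 11 of 22 and lower in none (12 higher and 0 lower adjusted over the list alone), such as PFKP (2.24 ± 0.18). Their median was 0.68 (adjusted p 4.85e-05). Of 24 matrix, adhesion and EMT genes, 12 responded higher in SW1736 and 2 lower (14 higher and 4 lower adjusted over the list alone). Their median was 0.74 (adjusted p 0.00118). Melanocyte and pigment genes responded lower in SW1736 in 11 of 21 and higher in none (0 higher and 12 lower adjusted over the list alone), and 9 of the 21 were detected by no probe in SW1736 at these times. Their median was -1.16 (adjusted p 9.38e-09). Of 22 amino acid and ER stress response genes, 10 responded lower in SW1736 and 2 higher (2 higher and 11 lower adjusted over the list alone), such as SLC3A2 (-2.45 ± 0.19). Their median was -0.62 (adjusted p 1.75e-05). Cholesterol synthesis genes responded lower in SW1736 in 3 of 16 and higher in none (0 higher and 3 lower adjusted over the list alone), such as HMGCS1 (-1.65 ± 0.30). Their median was -0.41 (adjusted p 0.014), and adjusted p = 0.161 with an estimated correlation. Of 22 interferon response genes, 6 responded higher in SW1736 and 1 lower (6 higher and 1 lower adjusted over the list alone). Their median was 0.32 (adjusted p 0.0361), and adjusted p = 0.227 with an estimated correlation. DUSP6 had another probe (0.19), detected on 0 of 12 arrays, that could not show a change.

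ERBB3 changed little in SKMEL28 against untreated cells, by -0.12 ± 0.19 at 1 h, -0.38 ± 0.19 at 6 h (adjusted p 0.299) and 0.32 ± 0.19 at 48 h (adjusted p 0.181), and none passed, while from 6 h to 48 h it rose by 0.70 ± 0.19 (adjusted p 0.00478). In SW1736 it changed by -0.15 ± 0.19 at 1 h, rose by 0.68 ± 0.19 at 6 h (adjusted p 0.0209) and changed by 0.43 ± 0.19 at 48 h (adjusted p 0.079). The response of ERBB3 differed between the lines at 6 h by 1.06 ± 0.26 (adjusted p 0.0172) and from 6 h to 48 h by -0.96 ± 0.26 (adjusted p 0.0122). These values are from its brightest probe. All 3 probes rose in SKMEL28 from 6 h to 48 h (0.80 and 0.82 on the others, adjusted p 0.00286 and 0.00294), but in SW1736 they disagreed at 6 h and 48 h. The 6 h difference was 0.18 and 0.32 on the others (adjusted p 0.871 and 0.727), and that from 6 h to 48 h was -0.79 (0.0605) and -0.85 (0.0483). The second changed by -0.05 ± 0.19 in SW1736 at 6 h and by 0.57 ± 0.19 in SKMEL28 at 48 h (adjusted p 0.0264 over all probes), and the third, not detected in SW1736, by 0.54 ± 0.20 in SKMEL28 at 48 h (adjusted p 0.0395). The SW1736 rise at 6 h passed with the replicate number as a block (0.683, adjusted p 0.00191). It did not pass without 0 h replicate 3 (0.44, adjusted p 0.131), 6 h replicate 1 (0.65) or 6 h replicate 2 (0.65). Nor did it pass with median scaling (0.54), SW1736 fitted alone (adjusted p 0.144) or array weights (0.0595). The 48 h change passed without 0 h replicate 1 (0.54), 0 h replicate 2 (0.55) or 48 h replicate 3 (0.61). It passed with that block (adjusted p 0.0134), without background correction, with the authors' values (0.049 in each) and without the third SW1736 arrays (0.0458). The 1 h change was 0.005 without 1 h replicate 3. Fitted alone, SKMEL28 passed at 6 h (adjusted p 0.0285) and 48 h (adjusted p 0.0186), and the 6 h difference between lines did not pass without SW1736 0 h replicate 3 (0.82).

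**Figure D3:**
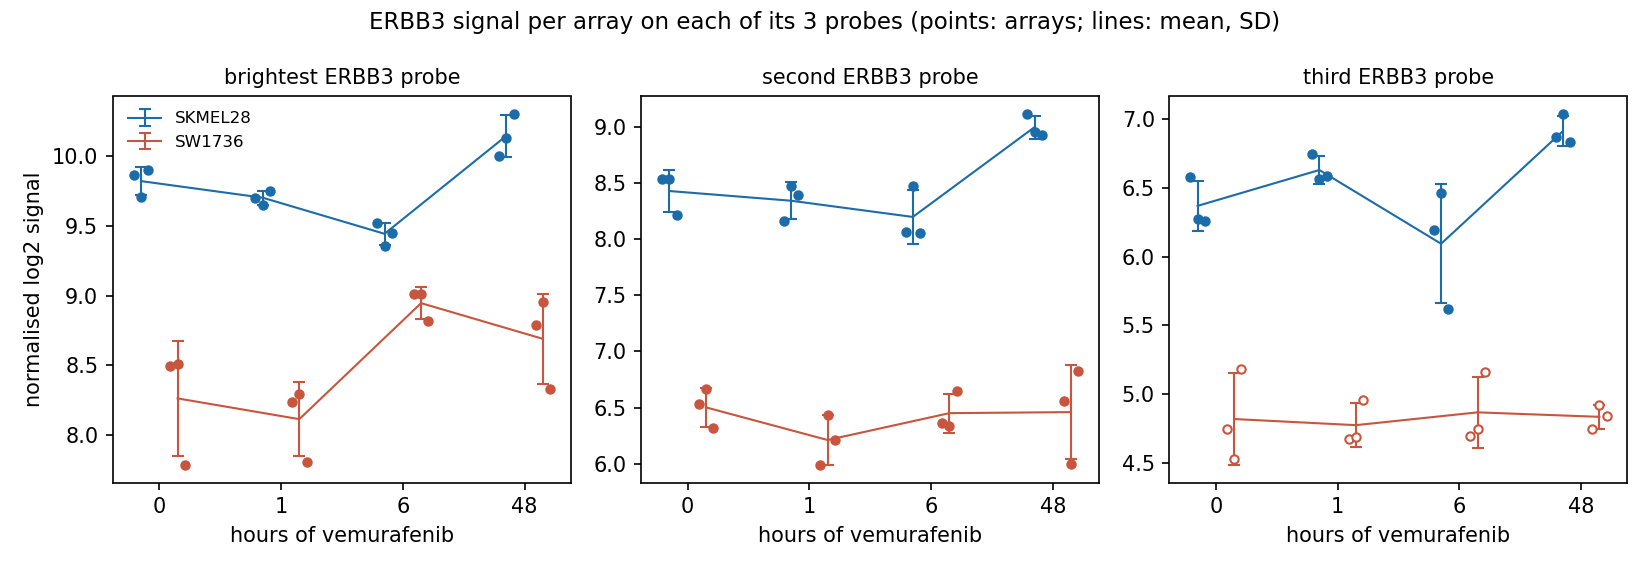
Normalised log2 signal of the 3 ERBB3 probes (panels) against hours of vemurafenib in SKMEL28 (blue) and SW1736 (red), with points for single arrays, lines joining means, SD bars and open points for arrays without detection. The brightest probe rose in SW1736 at 6 h and the second did not (-0.05), while the second and the third rose in SKMEL28 at 48 h.

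The ERBB3 ligand NRG1 fell in SW1736 by 1.37 ± 0.26 at 6 h and by 1.88 ± 0.26 at 48 h, and its response at 48 h differed from that of SKMEL28 by -1.35 ± 0.37 (adjusted p 0.011). This probe was not detected in SKMEL28 at 48 h, where another, detected on 3 of 3 arrays, gave a difference that passed too; the last (-0.52) did not pass. NRG3 rose in SKMEL28 at 48 h by 2.44 ± 0.24, a response that differed by -2.44 ± 0.33 in SW1736, which had 1 detection on 6 arrays, and TGFA, a ligand of EGFR, was at least 1.29-fold lower in SKMEL28 at 6 h and 1.33-fold at 48 h and fell in SW1736 by 1.16 ± 0.18 and 0.97 ± 0.18. HBEGF fell in SW1736 by 1.18 ± 0.25 at 6 h and 1.08 ± 0.25 at 48 h (detected on 1 of 3 arrays at each) and rose from 6 h to 48 h in SKMEL28 by 1.14 ± 0.25, and its response differed by -1.74 ± 0.36 at 48 h. Of 7 measured ERBB ligands 3 fell in SW1736 at 6 h (3 adjusted over the list alone; median -0.18, camera adjusted p 0.0115), a call lost without the third SW1736 arrays (adjusted p 0.0509). ERBB2, the partner of ERBB3, changed by 0.48 ± 0.17 in SKMEL28 (adjusted p 0.0281) and 0.56 ± 0.17 in SW1736 (adjusted p 0.0123) at 48 h; EGFR changed by -0.43 to 0.16 against untreated cells in SW1736, and none passed, but from 6 h to 48 h it rose there by 0.58 ± 0.19 (adjusted p 0.0277), as did its other probe (0.86, adjusted p 0.0103). In SKMEL28 this EGFR probe was detected on 1 of 3 arrays at 1 h and on none at the other times, so no fall could show. CTBP2, a corepressor, changed by -0.66 ± 0.20 at 6 h (adjusted p 0.043) and -0.58 ± 0.20 at 48 h (adjusted p 0.0296) in SW1736, and CTBP1 passed in neither line (0.05 and 0.25 in SKMEL28 and 0.06 and 0.18 in SW1736 at 6 h and 48 h). Other probes did not pass for NRG1 (-0.00 and -0.27 in SW1736 at 6 h and 48 h, detected on 3 and 1 of 6 arrays), TGFA in SKMEL28 (-0.50 and -0.25, on 1 of 6 each) and CTBP2 (-0.50 and -0.16 at 6 h and 48 h, on all 6, and 0.04 and -0.43, on 2 and 1).

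Several of these receptor and ligand calls lay near the threshold and were lost when any of several arrays was left out. The EGFR rise did not pass without SW1736 6 h replicate 1 (0.50) or 2 (0.59) or 48 h replicate 2 (0.44) or 3 (0.53), nor with median scaling (adjusted p 0.0907), SW1736 fitted alone (0.0529), array weights (0.104) or the third SW1736 arrays left out (0.0837). ERBB2 at 48 h failed in SKMEL28 without 0 h replicate 1 (0.45) or 2 (0.34) or 48 h replicate 2 (0.43) or 3 (0.43). Nor did it pass in SW1736 without 48 h replicate 1 (0.41), and median scaling ended both calls (0.34 and 0.35). CTBP2 failed at 6 h in SW1736 without 0 h replicate 1 (-0.68) or 2 (-0.53) or 6 h replicate 1 (-0.59) or 3 (-0.62). Nor did it pass at 48 h without 0 h replicate 1 (-0.60) or 2 (-0.45) or 48 h replicate 1 (-0.52) or 3 (-0.55). Its calls at 6 h and 48 h were lost with SW1736 fitted alone (adjusted p 0.141 and 0.0741), median scaling (0.0649 and 0.0503) and array weights (0.185 and 0.115), and that at 6 h also with no filter (0.054) and without the third SW1736 arrays (0.0509); array weights ended that of ERBB2 in SW1736 (0.0567). HBEGF changed by 0.66 ± 0.25 in SKMEL28 at 48 h (adjusted p 0.0406) and did not pass without 0 h replicate 1 (0.73), 2 (0.58) or 3 (0.67) or 48 h replicate 1 (0.62) or 2 (0.60), nor with median scaling (adjusted p 0.125) or no filter (0.0583). Its difference between lines from 6 h to 48 h (-1.03 ± 0.36, adjusted p 0.0461) did not pass without SKMEL28 6 h replicate 1 (-1.05), 2 (-1.11) or 3 (-0.93) or 48 h replicate 1 (-0.99) or 2 (-0.97), or SW1736 6 h replicate 2 (-0.80) or 48 h replicate 1 (-0.93) or 2 (-0.91). Median scaling (adjusted p 0.0527), no filter (0.0647) and the replicate number as a block (0.0517) ended this call too. EGF was detected on at most 1 of 3 arrays of each group at 6 h and 48 h. The ligands NRG4 (-0.35 to 0.16) and EREG (-0.36 to 0.11), detected on at most 1 of 3 arrays of each group, passed in none of the 6 comparisons with untreated cells.

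Of 24 lists and 6 comparisons with untreated cells, 45 of 144 camera tests passed, and 42 of them also with an estimated correlation; 17 of 20 did for 48 h against 6 h and 19 of 24 for the differences between lines. Receptor tyrosine kinases (lowest adjusted p 0.0768, SKMEL28 1 h), BCL2 family (0.15, SW1736 6 h), thyroid differentiation (0.205, SW1736 48 h), epithelial and keratin genes (0.264, SKMEL28 6 h), leukocyte and stromal markers (0.333, SW1736 48 h), ERBB3 regulators (0.0768, SW1736 6 h) and cholesterol synthesis (0.0627, SKMEL28 48 h) passed in none of the 6. Cholesterol synthesis nevertheless had 8 of 16 genes higher and none lower in SKMEL28 at 48 h (8 and 1 adjusted over the list alone), and leukocyte and stromal markers 3 of 9 and none in SW1736 at 48 h (4 and 1). No list call turned direction under another scaling or filter.

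Untreated SKMEL28 and SW1736 differed in 6883 genes, 3493 higher and 3390 lower in SW1736. The matrix protein EFEMP1 was higher in SW1736 by 8.11 ± 0.14, the actin bundler FSCN1 by 7.09 ± 0.19 and BASP1 by 7.06 ± 0.18, and the melanosome matrix protein PMEL (-8.98 ± 0.16), the transcription factor RUNX3 (-6.37 ± 0.27), the protease CTSK (-5.88 ± 0.30) and MITF (-4.60 ± 0.21) were lower. BASP1 in SKMEL28 and PMEL, RUNX3 and CTSK in SW1736 were detected on 2 of 3 arrays. ERBB3 (-1.56 ± 0.19), DUSP6 (-1.68 ± 0.21), SPRY4 (-2.95 ± 0.22), EGR1 (-1.33 ± 0.27) and HBEGF (-1.26 ± 0.25) were lower in SW1736 before treatment, and ERBB2 (0.69 ± 0.17), NRG1 (3.10 ± 0.26), TGFA (2.84 ± 0.18) and CTBP1 (0.60 ± 0.12) were higher, with adjusted p-values of at most 0.00151; EGFR was at least 11.2-fold higher. This NRG1 probe was detected on 1 of 3 SKMEL28 arrays. Other probes of NRG1 (0.49) and SPRY4 (-0.09), each detected on 1 of 6 arrays, and of CTBP1 (0.46 and 0.20) did not pass.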

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

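The tests of the second ERBB3 probe, of cells of another type and of ERBB3 without the third SW1736 arrays were chosen only after the result was seen. All values here are differences in response, SW1736 minus SKMEL28, that a test of the difference itself called between the lines, except the interferon and ERBB3 patterns, given as changes in SW1736 itself, and the probes without a symbol.

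The first pattern is the rise of ERK output from 6 h to 48 h, which was larger in SW1736 by a median of 0.565 (spread 0.227) over 20 genes. Normalization between arrays as the whole cause is argued against, since the median was 0.539 (spread 0.192) with median scaling, and so are the third SW1736 arrays, without which it was 0.657 (spread 0.246). A signal floor in SKMEL28 at 6 h stays open: over the 10 members detected throughout, the median was 0.501 with a spread of 0.413, which does not clear the bound set for it. A slower or weaker return of ERK activity in SKMEL28 may also account for it and was not measured.

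The second pattern is the interferon response, higher in SW1736 at 6 h than in untreated cells by a list median of 0.724. The third SW1736 arrays are argued against, since the median was 0.741 (spread 0.094) without them, and so is normalization, since it was 0.561 (spread 0.088) with median scaling. Cells of another type stay open: 1 of 9 measured leukocyte and stromal markers (CSF1R, 0.637) was higher at 6 h, but 3 were and none lower at 48 h (4 and 1 adjusted over the list alone; median 0.372, adjusted p 0.333 with camera and 0.0014 with fry), where the interferon list was higher too. SW1736 is a line grown in culture, and markers made by its own cells would count the same way, so the markers cannot decide this. A property of the lines may also account for the difference between them and was not tested, since each line is 1 genetic background.

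The third pattern is ERBB3 in SW1736 at 6 h, higher than in untreated cells on its brightest probe by 0.683. Background that compresses the second probe is argued against: that probe changed by -0.052 (SE 0.192), where the same factor would have given 0.61. The third SW1736 arrays as the whole cause are argued against, since the change was 0.509 (SE 0.135, adjusted p 0.0259) without these 4. Yet it was 0.444 (adjusted p 0.131) without SW1736 0 h replicate 3 alone. Adjusted p ranged from 0.0159 to 0.131 with 1 array out and from 0.00191 (replicate block) to 0.93 (second probe) otherwise. What the probes read may differ, such as transcript forms, and this stays open.

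The counts of genes with a different response were 3, 581, 2881 and 2491 at 1 h, 6 h, 48 h and 48 h against 6 h. Of 100 splits, 8, 3, 4 and 8 were as large, the real one included, and the highest others were 7, 1765, 3772 and 3154. The split with 1765 genes exchanges the times in 1 line, so it adds the responses of the lines where the real one subtracts them. The other splits as large kept the times of 1 line together and so hold its changes over time. They do not test a difference in response, so these shares cannot decide on chance. Splits that kept neither line's times reached at most 2, 1, 1 and 1 genes. For the comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05, and in each only the real split, 1 of 10, gave as many genes. In SKMEL28 the real counts and highest others were 24 and 0 at 1 h, 938 and 4 at 6 h, 5328 and 0 at 48 h, and 4509 and 0 for 48 h against 6 h. In SW1736 they were 29 and 6, 1193 and 23, 4692 and 4, and 3768 and 10, and for the untreated lines 6883 and 0.

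The other lists with a different response are given as medians. At 1 h immediate early genes differed by 0.215. At 6 h ERK output differed by 0.214, immediate early genes by 0.484, S phase and E2F targets by -0.429, melanocyte and pigment genes by -0.215, amino acid and ER stress response by 0.565, interferon response by 0.642 and inflammatory cytokines and NF-kB targets by 0.516. For ERK output at 6 h this sign goes against the medians of the lines themselves, -1.743 in SKMEL28 and -1.835 in SW1736. At 48 h ERK output differed by 0.849, S phase and E2F targets by 0.528, G2 and mitosis by 1.182, melanocyte and pigment genes by -1.533, cholesterol synthesis by -0.544, glycolysis and hypoxia by 0.608 and interferon response by 0.904. For 48 h against 6 h, S phase and E2F targets differed by 0.932, G2 and mitosis by 0.969, melanocyte and pigment genes by -1.159, amino acid and ER stress response by -0.624, cholesterol synthesis by -0.405, glycolysis and hypoxia by 0.676, interferon response by 0.315 and matrix, adhesion and EMT genes by 0.74.

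Single genes with a different response were DUSP6 (2.137), EGR1 (1.705), ERBB3 (1.06) and SPRY4 (2.822) at 6 h. At 48 h they were DUSP6 (3.196), EGR1 (1.22), NRG1 (-1.345), SPRY4 (3.111), CCND1 (0.742), MITF (-0.969), NRG3 (-2.436) and HBEGF (-1.735), and for 48 h against 6 h DUSP6 (1.059), ERBB3 (-0.957), NRG3 (-2.191), EGF (0.88) and HBEGF (-1.031). The probes these values come from were not detected for SPRY4 in either line or DUSP6 in SKMEL28 at 6 h, nor for NRG1 in SKMEL28 or NRG3 in SW1736 at 48 h, but other probes detected SPRY4 on 1 SW1736 array and NRG1 on 3 SKMEL28 arrays. EGF was detected on at most 1 of 3 arrays of each group at 6 h and 48 h. Its call (adjusted p 0.0417) was lost without background correction and with the authors' values (0.438, adjusted p 0.0712 in each), with median scaling (adjusted p 0.0721), no filter (0.0543), the trended prior (0.055), array weights (0.0765) and the replicate block (0.054). Leaving out 1 array, it passed only without SKMEL28 6 h replicate 1 or 48 h replicate 2 or SW1736 48 h replicate 2 or 3, at 0.569 to 0.919 without each of the others. Of 7777 tested probes without a gene symbol, 1437 changed at 48 h in SKMEL28 (782 higher, 655 lower). In SW1736 1300 did (640 higher, 660 lower). These are 18.5% and 16.7%, against 34.9% and 29.9% of probes with a symbol.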

How the results depend on the processing

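The third SW1736 arrays left out together and the other ERBB3 probes were tests chosen only after the data were seen. With 3 arrays per group, undetected genes gave bounds, or differences in response that rest on background values, and SW1736, the noisier line, shares its spread estimate with SKMEL28. The ERK output list kept its direction and its call in all 6 comparisons with untreated cells under every alternative run for it. Of 296 results for named genes none reversed under these alternatives, which for them do not include other probes (given below for ERBB3); 12 were no longer past the threshold with median scaling, 9 of 217 with each line alone, 7 with array weights, 5 of 192 without the third SW1736 arrays, 4 each with no filter and with the replicate block, 2 with the trended robust prior, and 1 each with no background correction and with the authors' values. Of 89 list calls, 85 to 89 were kept and none turned. The chip as a block was not run, because the tables do not name it.

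No background correction and the authors' values each gave ERBB3 0.335 in SW1736 at 48 h (adjusted p 0.049) and 12 genes responding differently at 1 h. Median scaling gave 14 genes in SKMEL28 and 19 in SW1736 at 1 h, ERBB3 0.535 in SW1736 at 6 h (adjusted p 0.148), and 1 gene responding differently at 1 h and 369 at 6 h. The mean of probes gave 5 genes responding differently at 1 h, as did the trended robust prior. Counting probes, which are more than genes, gave 8025 in SKMEL28 at 48 h, 6785 for 48 h against 6 h and 10704 between untreated lines. A 2-fold minimum, stricter by construction, gave 14, 325 and 2055 genes in SKMEL28 and 14, 322 and 1593 in SW1736 at 1, 6 and 48 h, 1529 and 1147 for 48 h against 6 h, differences of 1719 at 48 h and 1434 for 48 h against 6 h, and 3499 between untreated lines. An adjusted p under 0.01 gave 592 genes in SKMEL28 at 6 h, 8 and 573 in SW1736 at 1 h and 6 h, 2433 for 48 h against 6 h in SW1736, and differences of 1, 344, 1750 and 1391.

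Each line alone gave 1832 genes in SKMEL28 at 6 h, ERBB3 -0.377 (adjusted p 0.0285) at 6 h and 0.324 (adjusted p 0.0186) at 48 h there, and in SW1736 4 genes at 1 h, 489 at 6 h, 2462 for 48 h against 6 h and ERBB3 0.683 (adjusted p 0.144) at 6 h; the estimate of spread is the one thing this changes. Array weights (0.487 to 2.143) gave 70 and 2053 genes in SKMEL28 and 9 and 618 in SW1736 at 1 h and 6 h, ERBB3 0.318 (adjusted p 0.0346) in SKMEL28 at 48 h and 0.671 (adjusted p 0.0595) in SW1736 at 6 h, and 6 genes responding differently at 1 h. The third SW1736 arrays left out gave ERBB3 0.368 (adjusted p 0.0458) in SW1736 at 48 h and 5 genes responding differently at 1 h. The second ERBB3 probe gave 0.568 in SKMEL28 at 48 h and the opposite sign in SW1736, -0.052 at 6 h and -0.042 at 48 h; the third gave the opposite sign, 0.261, in SKMEL28 at 1 h and 0.544 at 48 h. Over alternatives other than single arrays, the adjusted p of ERBB3 ranged from 0.0285 to 0.705 at 6 h and 0.0186 to 0.668 at 48 h in SKMEL28, and from 0.00191 to 0.93 and 0.0134 to 0.912 in SW1736. Where no construction is named, the cause was not tested.

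The replicate block, a fixed effect for the replicate number within each line, gave ERBB3 0.427 (adjusted p 0.0134) in SW1736 at 48 h and 1 gene responding differently at 1 h. As a random effect (consensus correlation 0.0348) it moved no count by over 1.5 times. Arrays of 1 number correlated, after removing group means, by -0.023 to 0.074 in SKMEL28 (0 of 18 pairs over 0.1) and -0.002 to 0.179 in SW1736 (4 of 18, all replicate 3).

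Leaving out 1 array at a time gave 11 to 19, 687 to 754 and 4627 to 4696 genes in SKMEL28 and 12 to 26, 938 to 1104 and 4163 to 4298 in SW1736 at 1, 6 and 48 h, 3814 to 3932 and 3278 to 3413 for 48 h against 6 h, 1 to 5, 457 to 598, 2451 to 2806 and 2064 to 2448 responding differently, and 6280 to 6626 between untreated lines. The arrays behind the lowest counts at 1 h are given above. ERBB3 ranged from -0.177 to -0.081, -0.435 to -0.335 and 0.246 to 0.395 in SKMEL28, and from -0.387 to 0.005 (without SW1736 1 h replicate 3), 0.444 to 0.805 and 0.188 to 0.607 in SW1736. The arrays on which the ERBB3 calls in SW1736 depended are given with its results.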
